A study of Mus musculus with 6 samples.

How the data were processed

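RNA was sequenced from mouse embryonic stem cells of the C57BL/6 strain, which are pluripotent cells grown from the early embryo. Per the labels, 3 samples were wild type (WT) and 3 carried no working copy of Max (Max-KO), numbered 1 to 3 in each group. The labels' protocols state Trizol extraction and libraries made from total RNA with an Illumina TruSeq RNA kit. Whether the kit marked strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples.

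The deposited values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, with 1 value per gene and library with 2 decimals. Per the submitters' processing notes, the tools named were FastQC, HISAT2 2.1.0, RSEM and DESeq 1.26.0, with build GRCm38.p6. The notes as given here state neither the role nor the order of these tools, and no scaling across libraries was seen in the values. Each library listed 56689 identifiers, of which 55536 were Ensembl genes and 1153 were assembled loci without a gene name. Symbols, biotypes, lengths, GC content and coordinates came from the GENCODE M21 annotation of GRCm38, which held 55450 of the Ensembl identifiers, and the other 86 kept their identifier. A total of 25852 identifiers were listed at 0 in all 6 libraries.

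FPKM values do not state the depth, but low values kept a trace of it. In genes with 1 transcript, a low FPKM multiplied by the transcript length less 255 to 260 bases fell close to whole multiples of 1 step per library. The step and the length offset were those that brought these same values closest to whole multiples. Between 78.5% and 82.4% of the values then lay within 0.15 of a whole multiple. For a step fixed beforehand 30% would do so by chance, so the gap does not test the steps. The steps corresponded to an estimated 20.8 to 28.2 M fragments per library, so 1 FPKM in a transcript of 2 kb stood for about 36.2 to 49.0 fragments. Counts were not rebuilt from these steps.

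The test fixed in advance for count files was not used, because the files hold FPKM. The test fixed for a normalized unit took its place. Genes with a mean of at least 1 FPKM in at least 1 group were kept, 14661 in all, and assembled loci were left out. A gene with a mean under 1 FPKM in 1 group was kept only if higher in the other, so the filter set its direction. Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (trend and robust variance moderation, 2-sided), with the 2 genotypes as the only factor. A gene was called at a Benjamini-Hochberg adjusted p under 0.05; every adjusted p of a gene comes from this fit. Log2 differences are Max-KO minus WT on the log2(FPKM + 1) scale, which understates the change of genes with low values. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

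A set of 38 gene lists was fixed before the data were examined: pathways, complexes and markers of other cell types. The 37 lists with at least 4 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, against all genes tested, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the data and fry, a set test that asks whether members move 1 way on balance, were alternatives. The median log2 difference of all genes was not 0, so list medians are given less that of all genes tested (0.21) where the text says above or relative to all genes, and as they are where it says own median. A further 8 lists, among them gene families seen in a scan of 198 families sharing a symbol stem, were chosen after the data were examined and stand in the closing section.

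The rule for named genes, fixed at the same point, took 15 genes of interest, the 6 largest rises and 6 largest falls in log2 difference (among called genes without overlap between groups, leaving out predicted genes, clones and pseudogenes by name), the 3 largest gains and losses in FPKM, and up to 4 called members per list with 1 in the opposite direction. Members named without a value, where a count was 5 or fewer, were picked after their values were seen. The fit was tested on simulated data with 12950 genes and 200 planted changes. Of genes lowered 4-fold 98.0% were recovered (49 of 50), and of those lowered 2-fold 98.0% (48 of 49). Of those raised 2-fold 94.0% were recovered (47 of 50), and of those raised 4-fold 98.0% (49 of 50). Beside these, 20 of 12751 unchanged genes were called, so the share of false calls was above what the adjusted p threshold aims at. The planted changes were few and near balanced, and the median estimate of unchanged genes was 0.002. In the real data 9703 of 14661 genes were called and the median of all genes was 0.21. The simulation therefore does not test the fit where most genes change or all genes shift.

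Alternatives fixed in advance were quantile normalization, no filter, a stricter filter (mean of at least 5), limma without the trend, pseudocounts of 0.1 and 5, a replicate block, a correction for GC content and length, and leaving out each library. Chosen after seeing the data were median-ratio scaling, rescaling so that each library has the same sum (TPM), leaving out genes on X and Y, and nuclear protein-coding genes alone. The planned count-based alternatives could not be run without counts.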

Results

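The series compared messenger RNA levels of mouse embryonic stem cells with and without Max, the dimerization partner through which MYC proteins bind DNA and a subunit of the PRC1.6 repressor complex. There were 3 libraries of wild-type cells (WT) and 3 labelled Max-KO, all of strain C57BL/6. Summed FPKM was 755907 ± 16347 in WT (SD, n = 3) and 651596 ± 6602 in Max-KO, with an estimated 20.8 to 28.2 M fragments per library. Genes listed at 1 FPKM or more numbered 12750 ± 142 in WT and 14171 ± 59.4 in Max-KO (SD, n = 3). Log2 values of libraries of 1 group correlated across genes at 0.978 to 0.985, and those of different groups at 0.890 to 0.909.

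Max itself (ENSMUSG00000059436; GRCm38 chromosome 12, 76937269 to 76962201, minus strand) was listed in all 6 libraries. Its level was 41.6, 50.2 and 42.3 FPKM in WT 1 to 3 and 35.8, 39.6 and 43.4 FPKM in Max-KO 1 to 3, with overlapping groups. The log2 difference was −0.17 ± 0.10 (SE; 95% interval −0.40 to 0.06) and missed the threshold (limma, adjusted p = 0.168). It was −0.36 under median-ratio scaling, where it passed (adjusted p = 0.0135), and 0.06 after rescaling to TPM (adjusted p = 0.631). A gene-level FPKM does not show whether an exon is missing, so it does not check the genotype labels, and every direction here is that of libraries labelled Max-KO against those labelled WT.

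Germ cell genes showed the largest rises. Dazl, an RNA-binding protein of germ cells (ENSMUSG00000010592; chromosome 17, 50279395 to 50293636), rose from 2.27 ± 0.924 FPKM in WT to 360 ± 10.8 in Max-KO (SD, n = 3, log2 difference 6.82 ± 0.18 SE, limma adjusted p = 1.82e-06). Taf7l, a germ cell TFIID subunit (ENSMUSG00000009596; chromosome X, 134460118 to 134476490), rose from 0.433 ± 0.0551 to 113 ± 3.93 FPKM (log2 difference 6.32 ± 0.07). The other 4 of the 6 largest rises were Fkbp6 (1.41 to 143 FPKM), Spata22 (0.207 to 69.2), Nxf2 (0.283 to 63.7) and Mov10l1 (0.923 to 88.4). The largest falls were in Klhl13 (ENSMUSG00000036782; chromosome X, 23219271 to 23365082), which went from 278 ± 1.73 to 20.8 ± 2.84 FPKM (log2 difference −3.69 ± 0.09, limma adjusted p = 7.78e-07), and in Phlda2, Bhlhe40, Prph, Phgdh and Srm. Srm, the spermidine synthase, fell from 217 ± 16.0 to 24.3 ± 1.71 FPKM (SD, n = 3).

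Of 14661 genes tested, 6300 were higher and 3403 lower in the libraries labelled Max-KO (limma, adjusted p under 0.05), 9703 together. At an absolute log2 difference of at least 1, 2034 were higher and 713 lower. Groups did not overlap for 72.0% of genes, against 10% by chance. The median log2 difference of all genes was 0.21, and it moved with the scaling: 0.04 under median-ratio scaling, 0.43 after rescaling to TPM and −0.02 under quantile normalization. The share of calls that were higher was 64.9%, against 51.4%, 77.7% and 46.7% under these 3 scalings, so which direction held more calls depended on the scaling.

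**Figure D1:**
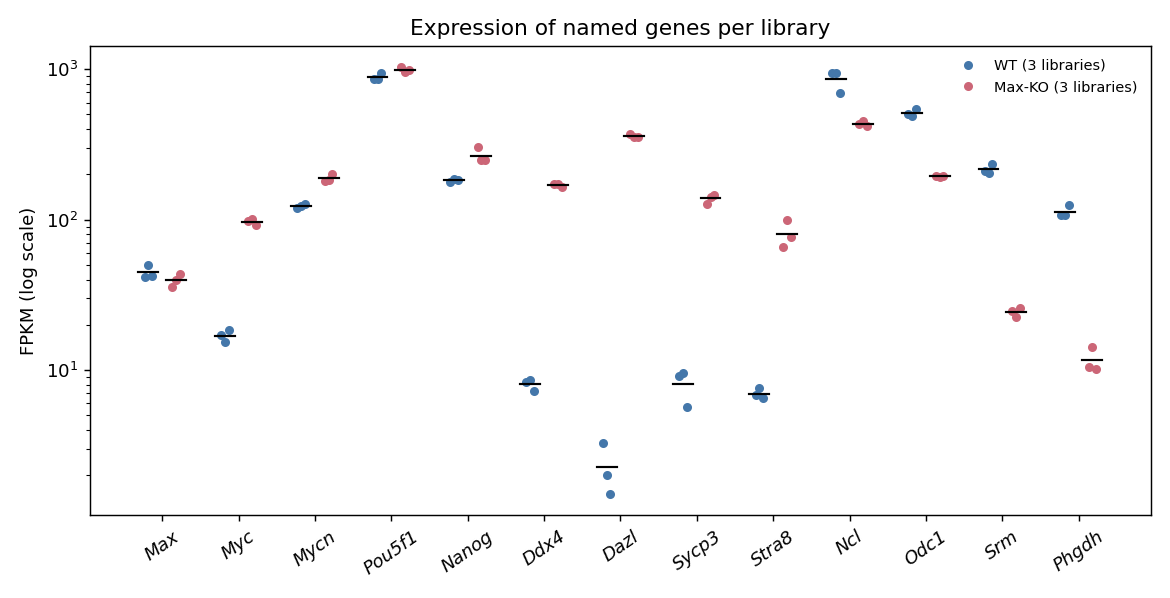
FPKM of 13 named genes (log axis) in each of the 3 WT and 3 Max-KO libraries; each point is 1 library and each bar the mean of 3. Max overlapped between the groups, with means of 44.7 and 39.6 FPKM, while Dazl went from a mean of 2.27 to 360 FPKM and Srm from 217 to 24.3.

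In the germ cell and piRNA pathway list, 30 of 36 tested members rose and 2 fell, Dppa3 and Tdrd12. The counts were the same adjusted over the list alone, and 23 rose at least 2-fold. Ddx4, an RNA helicase of the germ line, rose from 8.08 ± 0.701 to 170 ± 4.45 FPKM (SD, n = 3, log2 difference 4.24 ± 0.07, limma adjusted p = 2.57e-07). The list's median lay 2.15 above that of all genes (camera adjusted p = 3.70e-08, and 0.0820 with an estimated correlation). Members under 1 FPKM in WT, such as Taf7l and Mov10l1, passed the filter only through Max-KO, which fixed their direction. Dppa3, which is also active in naive embryonic stem cells, fell from 48.5 ± 1.56 to 16.9 ± 1.19 FPKM (SD, n = 3).

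Meiosis genes rose as well: 27 of 32 tested members were higher and 2 lower, Syce2 and Rec114, with the same counts adjusted over the list alone. The components of the synaptonemal complex Sycp1 (2.11 to 117 FPKM), Sycp2 (0.05 to 18.5) and Sycp3 (8.12 to 138) were among them. Sycp3 had a log2 difference of 3.96 ± 0.18 (limma adjusted p = 6.80e-06). Stra8, a regulator of entry into meiosis, rose from 6.98 ± 0.584 to 80.8 ± 17.5 FPKM (SD, n = 3, log2 difference 3.34 ± 0.15, limma adjusted p = 5.68e-06), and the cohesin subunit Stag3 from 6.44 to 115 FPKM. The median stood 1.10 above all genes (camera adjusted p = 7.44e-06, and 0.328 with an estimated correlation). Members under 1 FPKM in WT, such as Sycp2, passed the filter only through Max-KO, which fixed their direction. Y-linked genes rose in the same libraries, as given further on.

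Genes of the 2-cell-like state, a transient state of embryonic stem cells resembling the early embryo, rose in 23 of 24 tested cases, 22 of them at least 2-fold, and Eif1a fell (the same counts adjusted over the list alone). Zscan4f went from 0.01 to 26.1 ± 4.56 FPKM and Zscan4e from 0.0133 to 14.2 ± 3.45 (SD, n = 3). The list's median was 2.16 above all genes (camera adjusted p = 3.72e-07, and 0.331 with an estimated correlation). The 24 members summed to 111 FPKM in WT, of which Eif1a held 102, so most of the others were under 1 FPKM there. Those passed the filter only through Max-KO, which fixed their direction in advance, and the count and the list p partly reflect this. Zscan4 genes are near-identical copies that share reads, so levels of single members are uncertain. The fall of Eif1a, −0.30 ± 0.06, did not pass after rescaling to TPM (−0.07).

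Pluripotency genes stayed expressed. Nanog rose from 183 ± 3.45 to 266 ± 32.2 FPKM (log2 difference 0.53 ± 0.09, limma adjusted p = 1.34e-03) and Sox2 from 227 ± 11.01 to 330 ± 21.1 FPKM (0.54 ± 0.07, limma adjusted p = 3.73e-04; SD, n = 3). Pou5f1 was 891 ± 45.4 and 992 ± 34.7 FPKM, a log2 difference of 0.16 ± 0.06 that missed the threshold (limma adjusted p = 0.0517). It passed without WT replicate 3 (0.20, adjusted p = 6.58e-03), after rescaling to TPM (0.39), under quantile normalization (0.72), with the GC and length correction (0.46), with a pseudocount of 0.1 (adjusted p = 0.0498) and among nuclear protein-coding genes alone (adjusted p = 0.0456), and was −0.04 under median-ratio scaling. In the core pluripotency list 9 of 16 members rose and Utf1 fell (10 and 1 adjusted over the list alone), and camera did not call it (adjusted p = 0.161), except under quantile normalization (adjusted p = 7.06e-04). Naive pluripotency genes rose in 16 of 22 cases and fell in 3, Dppa3, Nr0b1 and Fgf4, with the same counts adjusted over the list alone. Tbx3 went from 4.30 to 32.0 FPKM, Tfcp2l1 from 27.4 to 80.9, Klf4 from 16.5 to 44.9 and Nr5a2 from 23.0 to 57.5. The naive list's median lay 0.46 above all genes (camera adjusted p = 0.0201, and 0.328 with an estimated correlation). Formative and primed epiblast genes split, with 8 higher and 7 lower of 20 (the same adjusted over the list alone, camera adjusted p = 0.649): Lefty1 fell from 219 to 60.7 FPKM and Dnmt3b from 85.5 to 39.8, while Sox3 rose from 1.04 to 4.75.

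The partners of Max did not move as 1 group. Myc rose from 17.0 ± 1.59 to 96.7 ± 4.58 FPKM (SD, n = 3, log2 difference 2.45 ± 0.08, limma adjusted p = 2.35e-06) and Mycn from 122.8 ± 3.90 to 188 ± 10.8 FPKM (0.61 ± 0.06, limma adjusted p = 1.15e-04). Mga, a MAX partner and PRC1.6 scaffold, rose from 59.0 ± 15.1 to 92.1 ± 4.603 FPKM (0.67 ± 0.19, limma adjusted p = 0.0193), a call lost without Max-KO replicate 2 (adjusted p = 0.0521) or Max-KO replicate 3 (adjusted p = 0.0613), under median-ratio scaling (adjusted p = 0.0506) and with the GC and length correction (adjusted p = 0.107). In the MYC-MAX-MXD network 5 of 13 members rose (with Mycl and Mxd1) and Mxi1 fell from 19.1 to 12.1 FPKM (the same counts adjusted over the list alone, camera adjusted p = 0.953). Its own median was 0.01 (−0.19 relative to all genes), against own medians of −0.08 under median-ratio scaling and −0.22 under quantile normalization. Of the 16 PRC1.6 subunits 8 rose and 3 fell, Tfdp1, Ehmt2 and Cbx3 (the same counts adjusted over the list alone, camera adjusted p = 0.900). E2f6 rose from 10.4 to 21.1 FPKM and Rnf2 from 50.4 to 96.2, while Tfdp1 fell from 121 to 71.8. This list's own median was 0.19 (−0.02 relative to all genes), and it was below 0, at −0.004, under median-ratio scaling. Among the other Polycomb genes 13 of 28 rose and 3 fell, Cbx7, Ezh1 and Rbbp7 (12 and 3 adjusted over the list alone, camera adjusted p = 0.615), with Epop up from 255 to 525 FPKM.

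Genes for making ribosomes fell together. In the ribosome biogenesis list 47 of 50 members fell and none rose (the same counts adjusted over the list alone), 18 of them at least 2-fold. Ncl, the nucleolar protein nucleolin, fell from 862 ± 142 to 435 ± 16.0 FPKM (SD, n = 3, log2 difference −0.97 ± 0.12, limma adjusted p = 3.75e-04), and the small nucleolar ribonucleoprotein subunits Nhp2 and Gar1 from 496 to 158 and from 163 to 59.1 FPKM. The list's median was −1.01 relative to all genes (camera adjusted p = 3.22e-19, and 0.0604 with an estimated correlation). All 20 aminoacyl-tRNA synthetases fell, also adjusted over the list alone, Vars from 107 to 30.8 FPKM and Sars from 161 to 73.2 (median −0.95 relative to all genes, camera adjusted p = 1.56e-11, and 0.0877 with an estimated correlation). Translation initiation and elongation factors fell in 22 of 25 cases (22 adjusted over the list alone), Eif5a from 1854 to 736 FPKM and Eef2 from 1579 to 730 (median −0.77 relative to all genes, camera adjusted p = 3.96e-11, and 0.0944 with an estimated correlation).

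Of 84 cytosolic ribosomal protein genes 79 fell and 3 rose (79 and 4 adjusted over the list alone). Rplp0 fell from 2712 ± 256 to 940 ± 18.9 FPKM and Rplp1 from 5896 ± 452 to 2339 ± 98.7 (SD, n = 3, log2 differences −1.52 ± 0.08 and −1.33 ± 0.07). The genes that rose were Rpl39l (2.30 to 33.6 FPKM) and Rpl10l, which are paralogs expressed in the testis, and Rpl7l1. The summed FPKM of all 84 genes fell from 20.5% to 14.5% of a library. The list's median stood at −0.87 relative to all genes (camera adjusted p = 1.63e-22, and 0.331 with an estimated correlation). Its own median of −0.67 was −0.13 under quantile normalization, where camera still called it (adjusted p = 4.49e-03). These genes share reads with pseudogenes.

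Biosynthetic and metabolic genes were also lower. In nucleotide and polyamine synthesis 28 of 30 members fell and none rose (29 and 0 adjusted over the list alone). Odc1, the first enzyme of polyamine synthesis, fell from 511 ± 31.8 to 194 ± 2.61 FPKM (SD, n = 3, log2 difference −1.39 ± 0.06, limma adjusted p = 4.44e-06), and Cad, which starts pyrimidine synthesis, from 82.3 to 18.1 FPKM. The median was −1.14 relative to all genes (camera adjusted p = 8.64e-16, and 0.0820 with an estimated correlation). Glycolysis genes fell in 20 of 24 cases, and Eno2 and Hk2 rose (the same counts adjusted over the list alone), the rise of Eno2 not passing under quantile normalization (0.37, adjusted p = 0.141). Eno1 fell from 1693 to 362 FPKM, Ldha from 1214 to 298 and the lactate carrier Slc16a3 from 213 to 26.1. Their median was −1.32 relative to all genes (camera adjusted p = 4.01e-09, and 0.257 with an estimated correlation). Cholesterol synthesis genes fell in 21 of 22 cases (21 adjusted over the list alone), Fdps from 198 to 56.6 FPKM and Dhcr7 from 39.4 to 10.99, with a median of −1.14 relative to all genes (camera adjusted p = 8.51e-12, and 0.0877 with an estimated correlation). The amino acid starvation response fell in 17 of 19 cases (17 adjusted over the list alone), with a median of −1.42 relative to all genes (camera adjusted p = 1.18e-10, and 0.0944 with an estimated correlation). Phgdh, the first enzyme of serine synthesis, fell from 113 to 11.6 FPKM, Ddit4 from 119 to 22.3 and Nupr1 from 22.5 to 2.38.

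Oxidative phosphorylation genes went both ways, 18 higher and 28 lower of 80 (the same adjusted over the list alone), with Sdhb down from 101 to 61.3 FPKM and Cox7b2 up from 0.260 to 4.08. Their own median was −0.09, or −0.30 relative to all genes (camera adjusted p = 7.79e-03, and 0.864 with an estimated correlation). It was 0.03 under quantile normalization and 0.14 after rescaling to TPM, and the call was lost in both. Mitochondrially encoded mRNAs had 4 of 13 members higher (mt-Nd2, mt-Nd4, mt-Nd5 and mt-Nd6) and mt-Atp8 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.649, but 6.36e-03 under quantile normalization), with an own median of 0.59 that was −0.16 after the GC and length correction. Mitochondrial genes held 4.66 ± 0.859% of summed FPKM in WT (SD, n = 3), with 3.67% in WT replicate 3, and 5.48 ± 0.209% in Max-KO. The level of mt-Nd5 rose from 605 ± 202 to 1731 ± 76.3 FPKM, among the 3 largest gains with Dppa5a (2510 to 4020 FPKM) and Gm10222 (3552 to 5625 FPKM). The largest losses were in mt-Atp8, Rplp1 and Eef1a1 (9098 to 6232 FPKM), whose call was lost under quantile normalization (−0.30, adjusted p = 0.104). Gm10222 is a nuclear copy of mitochondrial sequence and shares reads with it, so its level is uncertain. Its call was lost without Max-KO replicate 2 (log2 difference 0.63, adjusted p = 0.0590) and with the GC and length correction (0.24, adjusted p = 0.145). The call of mt-Atp8 was lost without WT replicate 1 (adjusted p = 0.103), WT replicate 2 (0.0991) and each of Max-KO replicates 1 to 3 (0.103, 0.0713 and 0.0766), and also with no filter (0.0638), after rescaling to TPM (0.267) and under quantile normalization.

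**Figure D2:**
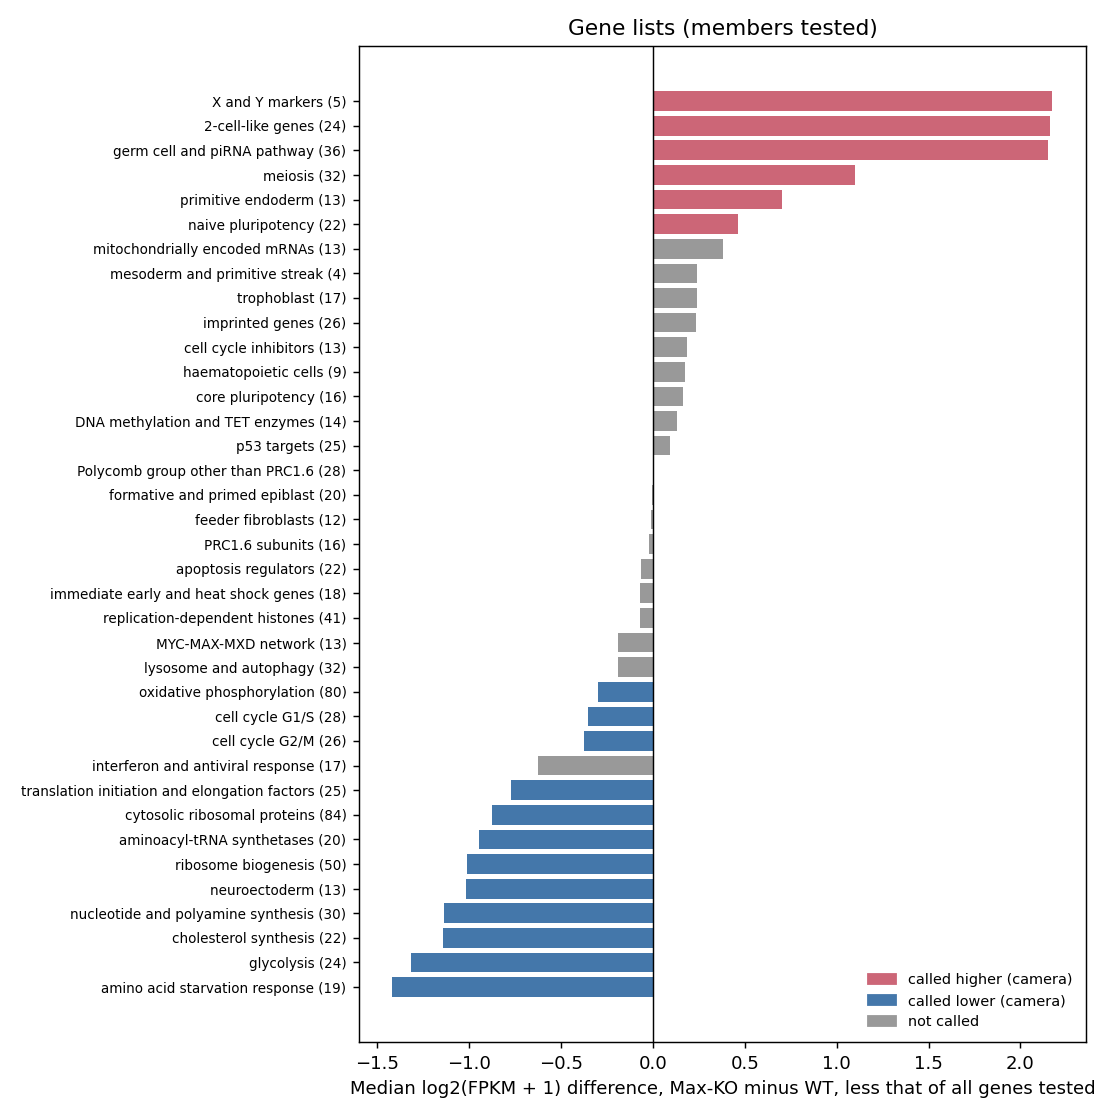
Median log2(FPKM + 1) difference of each of 37 gene lists (Max-KO minus WT, n = 3 each), less that of all genes tested; members tested in parentheses, and colours show the camera call at the preset correlation. The 2-cell-like list lies at 2.16 and the amino acid starvation list at −1.42; with an estimated correlation 0 of the 18 calls held, and the list's own median changes sign with the scaling for some lists, such as oxidative phosphorylation, G1/S and G2/M.

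Cell cycle genes went both ways. Of 28 G1/S genes 13 fell and 7 rose (the same adjusted over the list alone): Ccne1 fell from 114 to 36.7 FPKM and Mcm10 from 81.3 to 29.1, whereas Ccne2 rose from 8.14 to 19.6. The own median was −0.14, or −0.35 relative to all genes (camera adjusted p = 0.0163, and 0.384 with an estimated correlation), and it was 0.08 after rescaling to TPM. The call was lost there and under quantile normalization. Of 26 G2/M genes 13 fell, Aurka from 106 to 65.2 FPKM, and Bub1 rose from 51.0 to 63.1 (13 and 0 adjusted over the list alone). Leaving out Max-KO replicate 1, 2 or 3 ended the Bub1 call (adjusted p = 0.102, 0.119 and 0.0626), as did no filter, limma without the trend, median-ratio scaling and the GC and length correction. The own median of the G2/M list was −0.17, or −0.38 relative to all genes (camera adjusted p = 3.64e-04, and 0.0877 with an estimated correlation), and 0.06 after rescaling to TPM. The call was lost under quantile normalization (adjusted p = 0.0930). Cell cycle inhibitors had 6 higher and 4 lower of 13, the latter Gadd45b, Gadd45g, Cdkn1c and Cdkn2a (7 and 4 adjusted over the list alone, camera adjusted p = 0.900), with an own median of 0.39 (0.18 relative to all genes) that was −0.04 under quantile normalization, and a mean of −0.23 relative to all genes. Cdkn1a rose from 34.4 ± 1.44 to 45.4 ± 0.779 FPKM (0.39 ± 0.06, limma adjusted p = 7.16e-04), while Cdkn2a fell from 10.97 ± 0.867 to 7.02 ± 0.571 (SD, n = 3, −0.58 ± 0.10, limma adjusted p = 1.48e-03), a call lost with the GC and length correction (−0.22, adjusted p = 0.0678).

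Stress and death genes were mixed. Among p53 targets 14 of 25 rose and 5 fell, Bbc3, Bax, Sesn2, Gdf15 and Trp53 (the same adjusted over the list alone, camera adjusted p = 0.471), with Pmaip1 up from 29.2 to 125 FPKM and Bbc3 down from 17.4 to 9.25, a fall that the GC and length correction ended (−0.31, adjusted p = 0.152). The 22 apoptosis regulators had 8 higher and 8 lower (the same adjusted over the list alone, camera adjusted p = 0.812), with Bak1 down from 31.7 to 12.6 FPKM. Of 18 immediate early and heat shock genes 8 rose and 4 fell, Ier3, Atf3, Ier2 and Jund (the same adjusted over the list alone, camera adjusted p = 0.900). Egr1 rose from 6.93 to 43.1 FPKM and Ier3 fell from 59.7 to 12.7. Interferon and antiviral genes had 6 higher and 9 lower of 17 (the same adjusted over the list alone, camera adjusted p = 0.262), Bst2 falling from 81.7 to 8.74 FPKM and Ddx58 rising from 16.2 to 37.5. Lysosome and autophagy genes had 11 each way of 32 (the same adjusted over the list alone, camera adjusted p = 0.350), Lamp1 rising from 141 to 281 FPKM and Atg9b falling from 5.47 to 1.02. Under median-ratio scaling or quantile normalization the own medians of the apoptosis, immediate early and lysosome lists, above 0 as reported (−0.07, −0.07 and −0.19 relative to all genes), fell below 0 in at least 1 of these.

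Genes of chromatin and imprinting also moved singly. Among DNA methylation and TET enzymes 7 of 14 rose and 4 fell, Uhrf1, Dnmt3b, Tdg and Mbd3 (the same adjusted over the list alone, camera adjusted p = 0.885). Dnmt3l rose from 407 to 837 FPKM and Tet2 from 21.1 to 43.0, and Mbd3 fell from 115 to 46.6. Imprinted genes had 13 higher and 5 lower of 26, the latter Peg3, Phlda2, Grb10, Gnas and Cdkn1c (the same adjusted over the list alone, camera adjusted p = 0.649). H19, an imprinted noncoding RNA, rose from 0.647 ± 0.0551 to 55.1 ± 8.27 FPKM (SD, n = 3, log2 difference 5.08 ± 0.12, limma adjusted p = 7.36e-07), and Phlda2 fell from 103 ± 8.08 to 8.77 ± 0.559 FPKM. Replication-dependent histones had 10 higher and 2 lower of 41, Hist1h2ad and Hist1h3h (5 and 0 adjusted over the list alone, camera adjusted p = 0.921), with Hist1h1c up from 1.72 to 13.8 FPKM. Hist1h2ad lost its call without WT replicate 1 (adjusted p = 0.0732), WT replicate 3 (0.0757), Max-KO replicate 1 (0.0788) or Max-KO replicate 3 (0.0709), and Hist1h3h without WT replicate 2 (0.0873), WT replicate 3 (0.0944) or Max-KO replicate 3 (0.0817). Neither passed with no filter, a replicate block, TPM or the GC and length correction. The histone list had an own median of 0.14 (−0.07 relative to all genes), which was −0.02 under median-ratio scaling and −0.28 under quantile normalization.

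Markers of other cell types were uneven. Of 25 primitive endoderm genes 13 were testable. Of these 12 rose (12 adjusted over the list alone), Sparc from 218 to 473 FPKM, Col4a1 from 5.08 to 33.5 and Col4a2 from 1.997 to 11.7, and Rbp4 was not called. These 3 examples encode matrix proteins. The list's median was 0.70 above all genes (camera adjusted p = 1.61e-03, and 0.384 with an estimated correlation). Srgn, at 0.127 FPKM in WT, passed the filter only through Max-KO, which fixed its direction. Neuroectoderm genes fell in 9 of 13 cases and Nefm and Olig2 rose (the same counts adjusted over the list alone), Nefm not passing with a replicate block (adjusted p = 0.0524), with Stmn2 falling from 274 to 136 FPKM and Pax6 from 5.74 to 1.80. The median was −1.02 relative to all genes (camera adjusted p = 3.80e-03, and 0.328 with an estimated correlation), and the call was lost with the stricter filter (adjusted p = 0.121). Trophoblast genes had 9 higher and 3 lower of 17, Ascl2, Krt19 and Cdh3 (11 and 4 adjusted over the list alone, camera adjusted p = 0.627), with Gata3 up from 0.270 to 4.06 FPKM and the fall of Ascl2 not passing with the GC and length correction (−0.41, adjusted p = 0.0966). Only 4 of 20 mesoderm genes were testable, with Mesp2 and Snai1 higher and Kdr lower (the same adjusted over the list alone, camera adjusted p = 0.900), Snai1 rising from 1.32 to 5.34 FPKM and the rise of Mesp2 not passing under quantile normalization (0.26, adjusted p = 0.152). Only 3 of 39 Hox genes were testable, Hoxc4, Hoxc12 and Hoxc13. They rose (3 adjusted over the list alone), Hoxc12 from 0.0567 to 3.18 FPKM. Their summed level was 0.48 FPKM in WT and 7.16 in Max-KO. They thus passed the filter only through Max-KO, which fixed their direction in advance. The rise of Hoxc4 did not pass under quantile normalization (0.31).

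Feeder fibroblast markers had 4 higher (Col6a1, Col1a1, Timp3 and Col5a1) and 3 lower (Vim, Tagln and Acta2) of 12 (the same adjusted over the list alone, camera adjusted p = 0.900), Timp3 rising from 1.74 to 9.39 FPKM and Tagln falling from 20.4 to 3.40. Haematopoietic markers had 4 higher (Cd74, Csf1r, Laptm5 and Gata1) and 1 lower of 9 (the same adjusted over the list alone, camera adjusted p = 0.885), Cd74 rising from 2.34 to 11.3 FPKM and Coro1a falling from 10.4 to 3.21. The call of Csf1r was lost without WT replicate 1 (adjusted p = 0.0518) or WT replicate 2 (adjusted p = 0.0521), and under quantile normalization, where the log2 difference was 0.24 (adjusted p = 0.469) in place of 0.90. The own medians of the mesoderm, fibroblast and haematopoietic lists, 0.45, 0.20 and 0.38 (0.24, −0.01 and 0.17 relative to all genes), fell below 0 under quantile normalization.

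Sex chromosome markers differed between the groups. The Y-linked genes Ddx3y (1.01 ± 0.199 to 21.1 ± 2.92 FPKM), Eif2s3y (0.603 ± 0.247 to 22.6 ± 4.95) and Uty (0.653 ± 0.0709 to 7.63 ± 0.700) were higher in all 3 libraries labelled Max-KO than in any WT library (SD, n = 3, log2 differences 3.45 ± 0.13, 3.87 ± 0.19 and 2.38 ± 0.11). All 5 tested markers rose, with Kdm5d and Tsix (5 adjusted over the list alone), with a median 2.17 above all genes (camera adjusted p = 0.0134, and 0.355 with an estimated correlation). Only Ddx3y reached 1 FPKM in WT. The other markers passed the filter only through Max-KO, which fixed their direction in advance. The rise of Kdm5d did not pass under quantile normalization (0.19). Tsix overlaps Xist on the opposite strand, so its reads cannot be told apart from those of Xist, which was 0.123 FPKM in WT and 0.670 in Max-KO. Protein-coding genes on X had a median log2 difference 0.31 above that of autosomal genes, with 282 of 500 higher and 87 lower. With the GC and length correction the gap was 0.15.

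**Figure D3:**
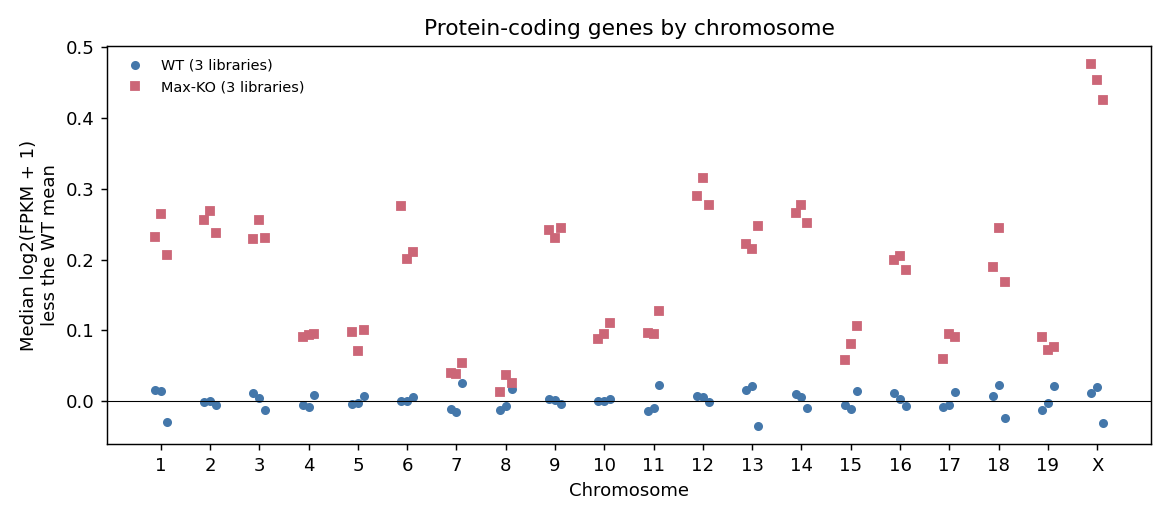
Median log2(FPKM + 1) of protein-coding genes on each autosome and X, less the mean of the WT libraries, in each of 3 WT and 3 Max-KO libraries (points). On X the Max-KO libraries lie at 0.48, 0.45 and 0.43; those on chromosome 8 lie at 0.01, 0.04 and 0.03, and the height of all Max-KO points moves with the scaling.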

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

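The tests that split the Y genes into Uty with Kdm5d and Ddx3y with Eif2s3y were chosen only after the pooled result was seen, as were median-ratio scaling and TPM.

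A signal outside the genes tested came from assembled loci without a gene name. Their summed FPKM was 7446 ± 1032 in WT and 13977.1 ± 1054 in Max-KO (SD, n = 3), or 0.985% and 2.15% of a library. Of 973 such loci with a mean of at least 1 FPKM in at least 1 group, 601 were higher and 58 lower without overlap between groups. This share of 67.7% compares with 72.0% of the genes tested and 10% by chance, so it was not particular to these loci. Loci at 1 FPKM or more numbered 435 ± 48.1 per WT library and 836 ± 24.1 per Max-KO library (SD, n = 3). Some loci thus passed only through Max-KO, which fixed their direction. Which transcripts these loci hold is not given in the sources used here, and no explanation was tested.

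Y-linked genes were higher in the libraries labelled Max-KO. A second active X in the WT cultures would lower X-linked genes in Max-KO, but X-linked genes lay 0.31 above autosomal ones, which argues against it. Reads of X homologues assigned to Y genes were weighed by the sum of both. Uty, Kdm5d and their homologues together gained 17.9 FPKM (spread 3.47), which moved reads alone would not give. The homologues Kdm6a (15.5 to 19.6 FPKM) and Kdm5c (40.7 to 46.6) rose themselves, so the sum cannot exclude such reads. Uty rose from 0.653 to 7.63 FPKM, out of proportion to Kdm6a, which argues against a fixed share for Uty. The sum also left this explanation open for Ddx3y and Eif2s3y, with a change of −46.3 FPKM (spread 28.3). It did so too for all 4 Y genes pooled (−28.3, spread 29.6). Ddx3x fell from 237 to 190 FPKM and Eif2s3x from 138 to 96.0, so a fixed share of their reads would have fallen too. Ddx3y rose from 1.01 to 21.1 FPKM and Eif2s3y from 0.603 to 22.6, which argues against a fixed share for these 2 genes. A share that differed between the groups was not tested. Lines of different origin, or loss of Y in the WT cultures, were not tested, and both would be confounded with genotype.

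Cytosolic ribosomal protein genes were lower in the libraries labelled Max-KO. Gene length and GC bias as the whole cause is argued against by a list mean of −0.56 after correction. Reads moved to pseudogenes are argued against too, since the summed FPKM of ribosomal protein pseudogenes also fell, to 0.633 of WT. Scaling stays open for the size of the fall, because the list mean, −0.62 as reported, was −0.14 under quantile normalization, −0.39 after rescaling to TPM and −0.81 under median-ratio scaling. All genes moved nearly alike under the last 2. The list's own median was −0.67 as reported, −0.44 after TPM and −0.86 under median-ratio scaling, beside 0.21, 0.43 and 0.04 for all genes. Quantile normalization brought the 2 medians closer (−0.13 and −0.02). The fall could therefore be smaller or larger than reported, and total RNA per cell was not measured.

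Germ cell and meiosis genes were higher in the libraries labelled Max-KO. Testis cells in the cultures are argued against by 30 markers of spermatids and testis somatic cells, whose median in Max-KO was 0.0489% of the level of Ddx4, with the spermatid genes Prm2, Tnp2, Akap4 and Odf1 listed at 0 in all 6 libraries. Of the other markers, the spermatid genes Tssk6 (1.16 to 2.31 FPKM) and Gsg1 (0.40 to 1.32) and the somatic Cyp11a1 (0.513 to 6.66 FPKM), Aard (17.6 to 64.8) and Star (1.33 to 4.07) were higher in all 3 Max-KO libraries and Rhox5 (85.6 to 30.1) and Acta2 (2.47 to 0.707) lower, all named after their values were seen. Length and GC bias is argued against by a meiosis list mean of 1.79 after correction. Early germ cells without spermatids, which these markers do not cover, and a difference between lines other than Max stay open and untested, since Y genes moved with the same libraries.

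The 6 libraries can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split was 1 of 10 with as many called genes (9703, highest other 3), 1 of 10 with as many at least 2-fold (2747, highest other 3) and 1 of 10 with as many lists (18, highest other 17). Each of the other splits called 13 to 17 lists by camera at the preset correlation while calling 0 to 3 genes. These splits mixed the genotypes unevenly, so part of the genotype difference remained in them. Their list counts therefore give no chance rate and cannot weigh the list calls. Those calls were lost with an estimated correlation between genes, so they remain uncertain.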

How the results depend on the processing

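Median-ratio scaling, TPM, leaving out X and Y genes and nuclear protein-coding genes alone were chosen after seeing the data. Of 3275 results for 185 named genes besides Max, 3218 kept their direction and side of the threshold, 50 lost the call, 6 gained it and 1 reversed: Pou5f1, −0.041 under median-ratio scaling. Of 662 list results, 654 kept their side of the threshold, with directions compared only for called lists and as camera gives them, 5 lost the call, 2 gained it and 1 reversed: oxidative phosphorylation under quantile normalization (adjusted p = 0.272). The own median changed sign for 14 of 37 lists under at least 1 of median-ratio scaling, TPM, quantile normalization and the GC and length correction, among them 3 called ones (oxidative phosphorylation, G1/S and G2/M). The Max transcript level was −0.36 under median-ratio scaling and 0.056 after rescaling to TPM. The stricter filter, which tests fewer genes, gave 3970 higher, while genes changed at least 2-fold in Max-KO numbered 1466, 946 of them higher. A pseudocount of 5, which shrinks low genes, gave 1014 at least 2-fold, 679 higher and 335 lower. At least 2-fold, quantile normalization gave 1115 higher and 1318 lower, and TPM 3132 higher. Camera with an estimated correlation called 0 lists, against 18 at the preset and 32 by fry. Apart from what the filter and pseudocount do by construction, the cause was not tested. Leave-one-out fits gave 8865 to 9420 genes (5783 to 6102 higher, 3082 to 3318 lower), 2584 to 2907 at least 2-fold (1884 to 2163 higher, 700 to 744 lower), 18 to 18 lists and a Max difference of −0.24 to −0.09. With a replicate block the count of genes changed in Max-KO was 9485, although nothing in the labels says that the numbers pair the libraries. Count-based tests (DESeq2, edgeR and voom) were not run without counts. At the estimated depth, 1 FPKM in a transcript of 2 kb rests on 36.2 to 49.0 fragments, which limits genes near the filter.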

Other observations

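The 8 lists in this part and their members were chosen after the data were examined, several from a scan of 198 gene families in these data, and the list of HIF targets was tested on genes other than those that led to the idea. All 9 tested members of the Xlr family, X-linked genes in near-identical copies, rose (Xlr4a from 0.0467 to 40.7 FPKM, Xlr3c from 0.173 to 31.0), with a median 4.54 above all genes (camera adjusted p = 2.18e-05 over the families scanned, and 0.762 with an estimated correlation). Only Xlr3a reached 1 FPKM in WT (1.12). The others passed the filter only through Max-KO, which fixed their direction in advance, so the count and the list p largely reflect this. Levels of single copies are uncertain, as they share reads. Of 34 Rhox genes 10 were testable, of which 7 rose and 2 fell, Rhox5 and Rhox6. Rhox13 went up from 0.753 to 60.1 FPKM and Rhox5 down from 85.6 to 30.1 (camera adjusted p = 0.543 over the families scanned, and 0.917 with an estimated correlation). Adjusted over the 8 lists alone, the Rhox p was 0.136, and from 0.0470 under median-ratio scaling, where it passed, to 0.326 after rescaling to TPM. Of 21 Mage genes 8 were testable, of which 6 rose, Mageb4 from 0.647 to 7.41 FPKM. Of 69 protocadherins 14 were testable, of which 13 rose, Pcdh15 from 3.10 to 39.7 FPKM, and Pcdh11x fell. Some of the 14, such as Pcdhga1 (0.72 FPKM in WT) and Pcdhgb7 (0.57), passed the filter only through Max-KO, which fixed their direction. The same held for most Rhox genes that rose, such as Rhox13 and Rhox10, and for some Mage genes, such as Mageb4 and Magea5. No list p is given for Mage genes and protocadherins, which were chosen after their values were seen.

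Mitochondrial ribosomal protein genes fell in 49 of 78 cases and rose in 2, with Mrpl12 down from 123.5 to 50.5 FPKM and a median of −0.55 relative to all genes (camera adjusted p over the families scanned 2.20e-06 for Mrpl and 1.43e-05 for Mrps genes, and 0.917 for both with an estimated correlation). Proteasome subunits fell in 21 of 38 cases, Psmb10 from 61.8 to 13.5 FPKM, and Psma8 rose from 10.98 to 17.2 (camera adjusted p over the families scanned 1.14e-03 for Psmb, 0.0352 for Psma and 0.307 for Psmd genes, and 0.917, 0.917 and 0.926 with an estimated correlation). The proteasome list had an own median of −0.22, which was 0.01 after rescaling to TPM, and under quantile normalization the list of 38 was not called (adjusted p = 0.292 over the 8 lists). Of the 351 genes in the scanned Zfp family, most of them zinc finger genes, 187 rose and 32 fell, Zfp229 rising from 3.18 to 44.5 FPKM. Over the families scanned it was not called (camera adjusted p = 0.0829, and 0.928 with an estimated correlation). The narrower list of 328 genes passed when adjusted over the 8 lists alone (camera adjusted p = 0.0127), but not under quantile normalization (0.214) or with the GC and length correction (0.203).

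Several genes that respond to low oxygen fell, among them Bhlhe40, Slc16a3 and Ldha, and the hypothesis was tested that targets of HIF, the hypoxia-inducible factor, were lower as a set. Among 24 HIF targets outside the genes already seen, 13 fell and 4 rose, with a median of −0.64 relative to all genes (camera adjusted p = 4.64e-04 over the 8 lists). Mif fell from 2034 to 557 FPKM, Fam162a from 98.4 to 23.9 and Vegfa from 17.7 to 5.61. With an estimated correlation the list missed the threshold (adjusted p = 0.157), so lower HIF activity stays a hypothesis that may equally reflect culture conditions, which were not tested.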
